A study of Homo sapiens with 2 samples.

How the data were processed

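The series compared a culture of the Caco2 line exposed to 20 mM mesalazine for 96 h with an untreated culture, and each group held 1 array. Groups were taken from the sample titles, which give no culture time for the untreated culture. Per the labels' protocols, total RNA was converted to biotin-labelled cRNA by the manufacturer's single-cycle procedure and hybridized to human U133 Plus 2.0 GeneChips. Per the submitters' processing notes, GCOS, the manufacturer's operating software, was used. Its version, algorithm and settings are not given in the sources used here.

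The authors deposited 1 signal intensity per probe set and array, on a linear scale, with no detection calls in the table used here. Both arrays held 54675 values. The lowest and highest were 0.0909 and 24387 on the untreated array, and 0.0670 and 25333 on the treated array. The mean after trimming 2% at each end was 150.02 and 150.018, so the deposited signals were already on a common scale and were used without further scaling. A scaling to a common trimmed mean corrects a difference in overall brightness and leaves any difference that depends on brightness. With no detection calls, a dim probe set could be judged only by its rank on its array.

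The lists, the rule for named genes, the size rule and 11 alternative settings were fixed before the data were examined. Signals under each array's median over the probe sets that are not controls (62 are controls) were raised to that median, which was 21.9 for the untreated and 27.2 for the treated array, and the log2 ratio of treated over untreated was taken. Floored ratios understate the difference of dim genes. Of the probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 had none. Those with 1 gene symbol were matched by gene identifier to current RefSeq names (annotation of assembly GRCh38.p14, used for names only), and 41043 matched. Genes on probe sets with several or no symbols were not analysed here. Each gene took the value of the probe set with the highest mean log2 signal, which gave 19775 genes, and a gene counted as measured when that probe set was at or above the floor on at least 1 array (13049 genes). Where 1 array was at the floor and the other above both floors the ratio is a lower bound. Where the treated signal was at its floor and the untreated signal lay between the floors, the floored ratio is above 0 by at most 0.31 although the treated signal was lower, and it bounds nothing.

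No significance test between the groups was run and no p-value was computed, since 1 array per group gives no spread between cultures. Genes were counted as higher or lower when the floored ratio was at least 2 in either direction. The technical spread was the SD of the difference in log2 ratio between paired probe sets of the same gene, divided by the square root of 2, over 5764 pairs above the floor on both arrays. It was 0.36. Each gene list was described by its median and by the percentile of that median among 10000 random lists of the same size (2000 in the alternatives) drawn within 20 bins of mean log2 signal. A list was called apart when its median lay outside the central 95% of its random lists. The 25 lists were written from textbook knowledge and covered brush border, Wnt targets and components, DNA replication, mitosis, growth arrest, p53 targets, enterocyte and secretory markers, PPAR targets, NF-kB targets, amino acid response, NRF2, xenobiotic metabolism, cholesterol synthesis, hypoxia, iron, junctions, mesenchymal genes, apoptosis, interferon response, ribosome, respiratory chain, fibroblasts and leukocytes. Some genes belong to more than 1 list.

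Named genes were the 12 highest and 12 lowest ratios among genes whose brighter signal reached the 60th percentile of its array and whose other measured probe sets all differed in the same direction, a panel of 12 genes fixed whatever their values, and in each list up to 4 members with the largest ratios. RABGEF1P1, EXD3, RGS5 and FABP7 had ratios in that range and were left out of the top genes because another probe set went the other way. Other list members beyond the leading 4 were named after their values were seen. These were MME, DDIT3, DDIT4, VLDLR, MTHFD2, HSPA5, HSP90B1, HYOU1, PDIA4, TKT, NQO1, AKR1C3, GSTA1, OAS1, IFIT3, DNAJB9, CALR, COL1A1, COL1A2, VIM, SESN2, SLC7A5, ATF4, HERPUD1, XBP1, SEL1L, NOTUM, RNF43, VSNL1, HMOX1 and TALDO1, and their single ratios were not computed under the alternatives.

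The procedure was tested on simulated arrays of 12580 genes with the measured technical SD of 0.36. Among 200 genes with a known change, the size rule recovered 10% of those changed 1.5-fold, 58% at 2-fold, 100% at 3-fold and 100% at 4-fold. Of 12380 unchanged simulated genes 33 were called higher and 16 lower, and 8 of 200 unchanged lists stood apart. The simulation gave every probe set the same SD, and changes were set only in genes above the floor on both arrays. In the data the SD of the log2 ratio was 0.73 in bin 2 of 10 bins by brightness and 0.35 in the brightest bin. The simulated rates therefore do not carry over to dim genes, and they hold no spread between cultures. The alternatives were 4 other scalings (centring on the median ratio, quantile normalization, loess of ratio on brightness with a span of 0.3, and centring on 100 normalization control probe sets), floors at the 25th and 75th percentile, no floor, the median over a gene's probe sets, leaving out probe sets with the suffixes for shared or cross-hybridizing sequence, and ratios of 1.5 and 3. One floor for both arrays was added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.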

Results

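Gene expression was measured in Caco2, a human colorectal adenocarcinoma line that can take on features of small intestinal enterocytes in culture. One culture had been exposed to mesalazine (5-aminosalicylic acid, an anti-inflammatory drug used in ulcerative colitis) at 20 mM for 96 h. The other was labelled untreated, with no culture time given. A difference in culture time can therefore not be told apart from mesalazine in any value below. Each group held 1 array, so there were no replicates, no p-value could be given, and every ratio compares these 2 arrays. The arrays were human U133 Plus 2.0 GeneChips with 54675 probe sets, and the deposited values were linear signal intensities. The number of arrays limits the precision. The trimmed mean signal was 150.02 on the untreated array and 150.018 on the treated array, and the median signals were 21.9 and 27.2. A gene was measured when its brightest probe set reached the median signal of at least 1 array, and signals under an array's median were raised to it before ratios were taken. Of 19775 genes with a probe set of their own, 13049 were measured.

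The comparison asked which transcripts differed in Caco2 cells after mesalazine, a drug studied for its effects on proliferation, on beta-catenin and on the protocadherin-family gene CDHR5 in colorectal cancer cells. CDHR5, a brush border cadherin also called mu-protocadherin, had a signal of 43.2 without and 131 with mesalazine, 3.04-fold higher. The cystine transporter gene SLC7A11 (318 to 1088), the asparagine synthetase gene ASNS (1135 to 4680) and the brush border peptidase gene DPP4 (81.4 to 313) were also higher in the treated array. CTNNB1, which encodes beta-catenin, was 2.24-fold lower on its brightest probe set (969 to 432), and inside 2-fold with the median over its probe sets (log2 ratio −0.36), 1 of which was higher (63.0 and 81.7). The remaining CTNNB1 probe set had 35.0 and 14.5, with the treated signal under the floor, so that median is limited by the floor. Genes of DNA replication and mitosis mostly lay a little below 0, with list medians of −0.35 and −0.24 on the log2 scale.

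By the size rule of a ratio of at least 2, 617 genes (4.73% of those measured) were higher with mesalazine and 233 (1.79%) were lower. The untreated signal lay under the floor for 184 of the higher genes and the treated signal for 33 of the lower ones, so those ratios are lower bounds and are written as "at least". Of these 850 genes 72.6% were higher. That split depended on the scaling: it was 380 higher and 331 lower after quantile normalization (53.4% higher), 371 and 332 after a loess correction for brightness (52.8% higher) and 741 and 179 when centred on the 100 normalization control probe sets (80.5% higher). Dim genes carried the excess. When the genes were divided by brightness into 10 bins of equal size, the 5 dimmer bins held 543 higher and 144 lower genes and the 5 brighter bins held 74 and 89. The treated array's floor was itself higher by 0.31 on the log2 scale. With 1 floor for both arrays, a setting added after the data were seen, 481 genes were higher and 233 lower (67.4% higher).

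**Figure D1:**
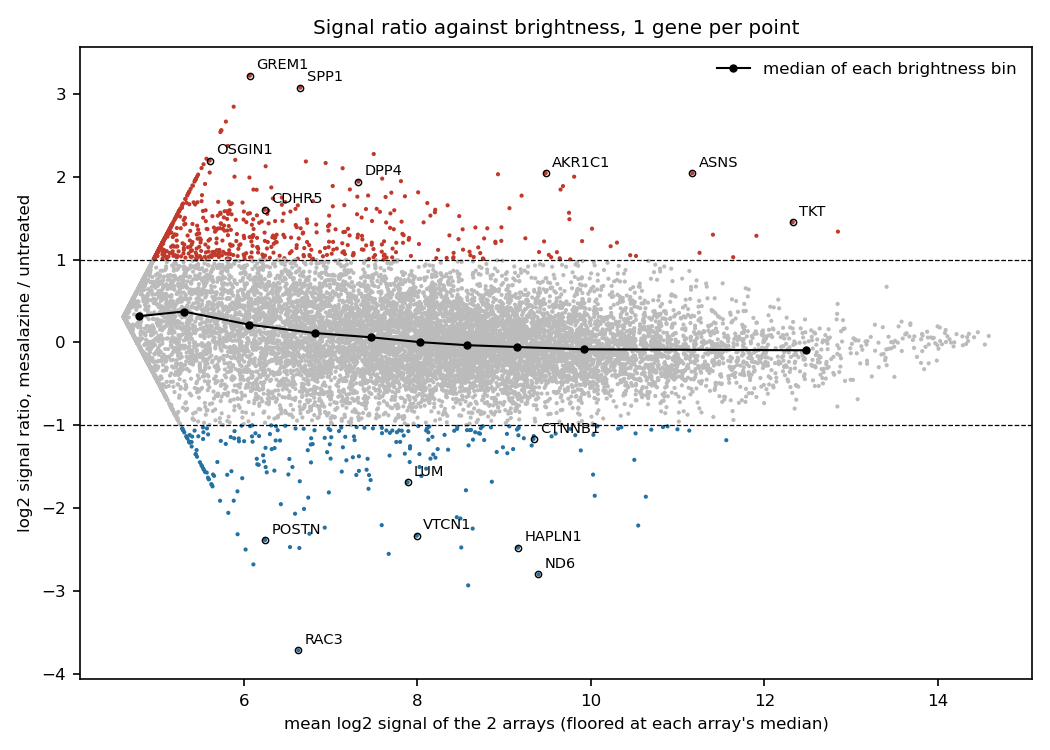
Log2 signal ratio of mesalazine over untreated (y axis) against the mean log2 signal of both arrays (x axis), with 1 point per measured gene, signals floored at each array's median, red for genes at least 2-fold higher (617), blue for genes at least 2-fold lower (233) and dashed lines at the size rule. The black line joins the medians of 10 bins of genes by brightness and runs from 0.32 in the dimmest, which is about the 0.31 between the floors of the arrays, to −0.09 in the brightest.

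The technical spread, taken from 5764 pairs of probe sets for the same gene, had an SD of 0.36 on the log2 scale, or 1.28-fold. A ratio of 2 is a log2 value of 1, above 2 such SDs (0.72), for probe sets above the floor on both arrays. Only those entered the pairs, and error shared by both probe sets of a gene cancels in their difference. Among dim genes the ratios were wider. Their SD was 0.73 in brightness bin 2, with 298 higher and 41 lower genes, and 0.35 in the brightest bin. Those SDs also hold any real differences, so the technical spread of dim genes is not known. The SD from pairs holds no spread between cultures. A further measured probe set existed for 211 of the higher genes, and it was higher for 188 of them and at least 2-fold higher for 83. Among the lower genes 110 had a further measured probe set, which was lower for 92 and at least 2-fold lower for 33. The 18 hybridization control probe sets had log2 ratios between −0.11 and 0.14. The correlation of log2 signals across the 24904 probe sets above the floor on both arrays was 0.962, a value across probe sets, which are not independent replicates. The 3′ to 5′ signal ratio of GAPDH was 1.09 in the untreated and 1.04 in the treated array, and that of ACTB was 1.39 and 1.53.

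The genes with the largest floored ratios that passed the brightness and probe set criteria are given here, and those known only as bounds have no order among themselves or against the others. GREM1, a secreted antagonist of bone morphogenetic proteins, had 20.6 and 205 (at least 9.33-fold higher). SPP1, which encodes the secreted phosphoprotein osteopontin, had 34.5 and 291 (8.44-fold). The chloride intracellular channel family gene CLIC5, known from microvilli and stereocilia, had 16.6 and 158 (at least 7.20-fold). BEAN1 (16.4 and 139), the long non-coding RNA LINC-PINT (15.4 and 130) and the stress-induced chromatin protein gene NUPR1 (20.7 and 128) were at least 6.36-fold, 5.91-fold and 5.82-fold higher. The smooth muscle actin gene ACTG2 (24.7 to 128) and the tetraspanin-like surface protein gene TM4SF1 (82.0 to 397) were 5.18-fold and 4.85-fold higher. The beta-defensin gene DEFB124 (12.2 to 102) was at least 4.66-fold higher, and the oxidative stress response gene OSGIN1 (22.7 to 104), the retinoid-responsive gene RARRES1 (49.2 to 224) and the tubulin gene TUBE1 (58.0 to 260) were 4.58-fold, 4.55-fold and 4.49-fold higher. All 3 measured probe sets were higher for TM4SF1, RARRES1 and CLIC5. For these genes and the lower genes below, agreement in direction of the measured probe sets was a condition of selection.

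Among the lower genes, RAC3 had 358 without and 21.8 with mesalazine (at least 13.2-fold lower, from its single probe set). The mitochondrially encoded complex I gene ND6 had 1778 and 255 (6.97-fold lower), also from a single probe set. The teneurin gene TENM4 (174 and 18.8) was at least 6.41-fold lower, the homeobox cluster antisense RNA HOXB-AS3 (493 and 84.0) 5.87-fold lower and the retinal lipid transporter gene ABCA4 (154 and 25.5) at least 5.66-fold lower. HAPLN1, a link protein that holds hyaluronan to proteoglycans, had 1350 and 242 (5.57-fold lower, all 4 measured probe sets lower), the hyaluronan synthase gene HAS2 217 and 39.2 (5.54-fold lower) and the matrix protein gene POSTN 173 and 33.1 (5.22-fold lower). LRRN4 (235 and 42.1), the T cell inhibitory ligand gene VTCN1 (572 and 113) and BCL7C (240 and 48.5) were 5.59-fold, 5.04-fold and 4.96-fold lower, and the non-coding RNA LINC03024 (136 and 3.18) at least 4.98-fold lower.

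With the floor at each array's 75th percentile, which sets more signals to the floor, GREM1, CLIC5, RARRES1, TUBE1, TENM4, ABCA4, LRRN4, HAS2, POSTN and BCL7C lay inside 2-fold. BEAN1, LINC-PINT, NUPR1, ACTG2, DEFB124, OSGIN1 and LINC03024 lay under that floor on both arrays (139 untreated, 148 treated) and had no ratio there. HOXB-AS3 had a ratio of 1.99 when its probe sets were summarized by their median, and HOXB-AS3 and POSTN lay inside 2-fold without probe sets that can hit several transcripts. The POSTN probe set used there had 38.1 and 6.05, with the treated signal under the floor, so its ratio is a lower bound. A dim HOXB-AS3 probe set (39.0 and 16.6) also had its treated signal under the floor, which limits the median of 1.99.

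Each of 25 gene lists was described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists matched on brightness. A list stood apart when its median lay outside the central 95% of the random lists. Of the 10 alternatives that apply to lists, 2 are centrings that shift every gene alike and cannot change a percentile except through the newly drawn random lists. There were 7 lists apart on the higher side and 4 on the lower side, where random draws of unrelated genes would give 1.25 in all. Members of a list can vary together and some genes belong to several lists. The 1.25 therefore does not measure how often lists differ between untreated cultures.

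**Figure D2:**
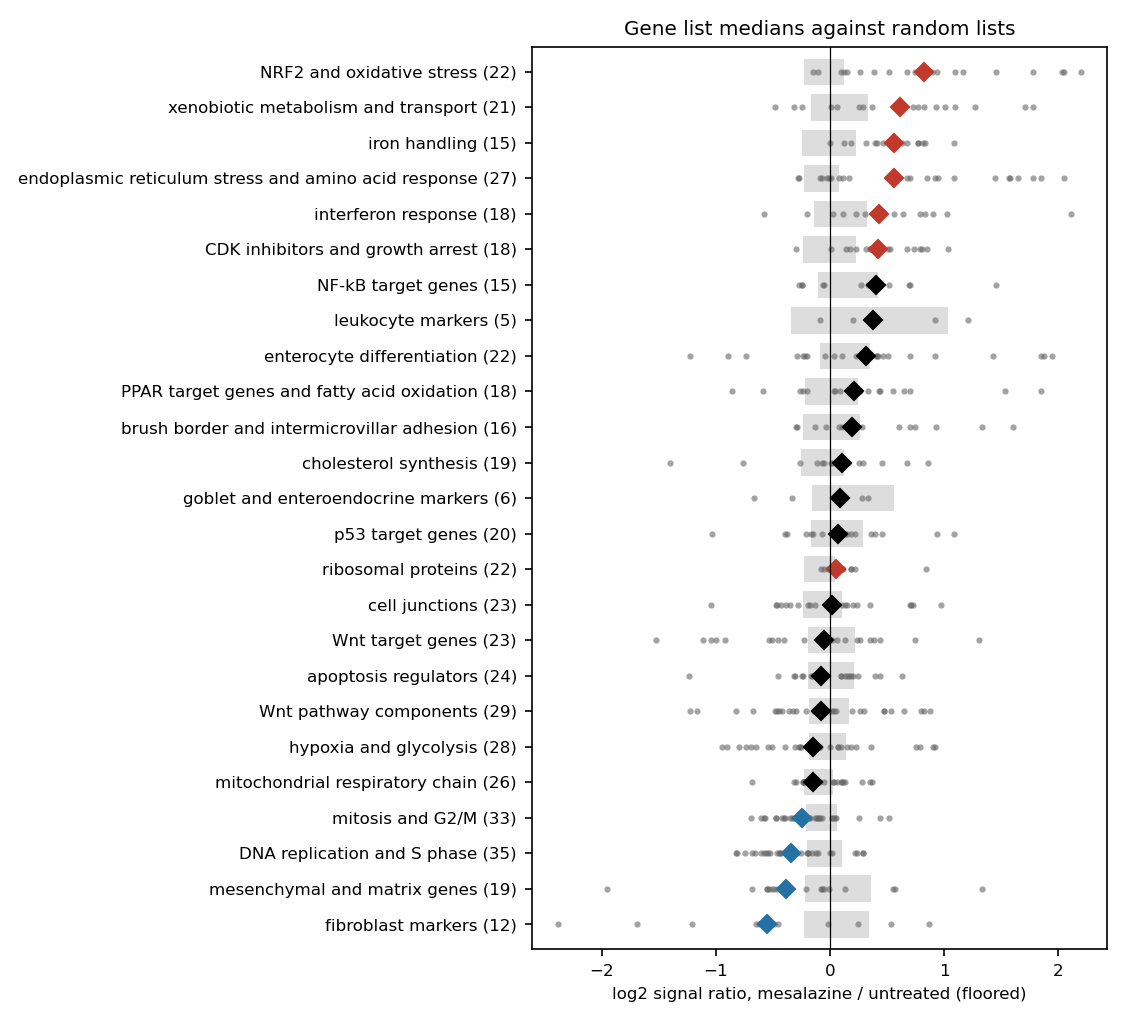
Log2 signal ratio of mesalazine over untreated (x axis) for each gene list (y axis, with the number of measured genes in parentheses), where grey dots are single genes, diamonds are list medians and grey bars span the central 95% of 10000 random lists. Red diamonds lie above that span and blue ones below it, with medians from 0.82 for NRF2 and oxidative stress to −0.55 for fibroblast markers.

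Brush border genes leaned to higher signals without the list standing apart. Of 16 measured members 12 lay above 0 and 2 were at least 2-fold higher, with a list median of 0.20 (percentile 92.5). CDHR5 was higher on all 3 of its probe sets, with 38.2 and 122 on the next brightest and 3.46 and 49.8 on the dimmest. It stayed at least 2-fold higher under all 9 alternatives that measured it, with log2 ratios from 1.18 to 1.67. PDZK1, a scaffold protein gene of the apical membrane, was 2.51-fold higher (47.6 to 119). The scaffold gene NHERF1 (764 and 1457) and the calmodulin-like gene CALML4 (446 and 745) had ratios of 1.91 and 1.67. Without probe sets that can hit several transcripts, 11 members were left and the list stood apart (median 0.61, percentile 99.55). It did not stand apart under the other 9 alternatives, where the lowest percentile was 73.5.

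Among 22 measured genes of enterocyte differentiation 4 were at least 2-fold higher, and the list median was 0.31 (percentile 95.2, not apart). The higher genes were DPP4 (3.84-fold), the membrane mucin gene MUC13 (41.6 to 152, 3.66-fold), the chloride/bicarbonate exchanger gene SLC26A3 (78.6 to 283, 3.60-fold) and the carbonic anhydrase gene CA2 (77.3 to 207, 2.68-fold). The endopeptidase gene MME was 2.34-fold lower (169 to 72.4). The list stood apart under 4 of the 10 alternatives, with a percentile of 98.1 at the 25th percentile floor, 98.25 with no floor, 99.25 with the median over probe sets and 97.875 without probe sets that can hit several transcripts. The median was 0.11 (percentile 67.3) with 1 floor for both arrays, 0.12 (87.85) after the loess correction and 0.13 (90.05) after quantile normalization. Only 6 of the goblet and enteroendocrine markers were measured, none past 2-fold, with a median of 0.09 (percentile 19.8). The trefoil factor genes TFF1 (72.7 and 57.6) and TFF3 (74.7 and 90.7) were among them. MUC2, the main secreted intestinal mucin, had 25.7 and 3.31, with the treated signal under the floor. Because the treated array's floor was the higher of the pair, a gene such as MUC2 can have a floored ratio above 0 with a lower treated signal, and no fold is given for it. The median of the goblet and enteroendocrine list rests partly on that MUC2 ratio. The list median was −0.10 after quantile normalization and −0.13 after the loess correction.

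Wnt target genes did not stand apart as a group. Of 23 measured members 10 lay above 0 and 13 below, with a median of −0.05 (percentile 28.7). The median was −0.16 (percentile 5.7) after quantile normalization, −0.18 (5.35) after the loess correction and −0.23 (5.45) at the 75th percentile floor. The list stood apart under none of the 10 alternatives. The transcription factor gene PROX1 was at least 2.87-fold lower (78.2 and 18.1), the pseudoreceptor gene BAMBI 2.17-fold lower (1538 to 710) and the Wnt inhibitor gene APCDD1 2.06-fold lower (1248 to 606), while the urokinase receptor gene PLAUR was 2.46-fold higher (23.8 to 58.5). The next largest differences were those of NOTUM (535 and 268) and RNF43 (314 and 166), both lower, and VSNL1 (81.0 and 136), which was higher. AXIN2, a direct feedback target of the pathway, had nearly equal signals (2635 and 2666). MYC had 842 and 1011 (ratio 1.20). CCND1, the cyclin D1 gene, had 440 and 304, and its other probe set 238 and 123. APCDD1 was inside 2-fold after the loess correction, with centring on the normalization controls and with the median over probe sets.

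The 29 measured Wnt pathway components had a median of −0.08 (percentile 24.6), with 13 above 0 and 16 below. Under the 10 alternatives the percentile ran from 2.725, close to the cut of 2.5, to 37.2, and the list stood apart in none. The receptor gene FZD1 was 2.34-fold lower (194 to 82.9), with 48.6 and 60.2 on its other probe set. CTNNB1 was 2.24-fold lower on its brightest probe set, and its dimmer ones gave 63.0 and 81.7, and 35.0 and 14.5. The CTNNB1 log2 ratio was −0.36, inside 2-fold, when its probe sets were summarized by their median. The treated signal of 14.5 on its dimmest probe set lay under the floor, so that median is limited by the floor. TCF7L2, the main TCF factor of the intestine, had 2121 and 1835. AXIN1 (65.9 and 121) and the corepressor gene TLE3 (557 and 315) had the next largest differences.

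Both proliferation lists stood apart on the lower side, though no single member passed 2-fold. In the DNA replication and S phase list 29 of 35 measured genes lay below 0, with a median of −0.35 (percentile 0.02). The DNA polymerase epsilon genes POLE (314 and 178) and POLE2 (372 and 231), the methylation maintenance factor gene UHRF1 (489 and 279) and the ribonucleotide reductase gene RRM2 (2096 and 1250) had the largest differences. In the mitosis and G2/M list 26 of 33 lay below 0, with a median of −0.24 (percentile 0.88), and the kinetochore motor gene CENPE (344 and 212) and the mitotic transcription factor gene FOXM1 (740 and 487) led. Both lists stood apart under all 10 alternatives.

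Genes of CDK inhibition and growth arrest stood on the other side. Of 18 measured members 17 lay above 0, the median was 0.42 (percentile 99.96), and the list stood apart under all 10 alternatives. CEBPB was 2.04-fold higher (2235 to 4565), the stress sensor gene GADD45A had 390 and 703, and the p15 inhibitor gene CDKN2B had 27.1 and 47.4. The p21 gene CDKN1A (140 and 180), KLF4 (810 and 947) and CEBPA (1322 and 1876) had ratios of 1.29, 1.17 and 1.42. The p53 target list had a median of 0.07 (20 measured, percentile 57.0), with GDF15 2.12-fold higher (49.1 to 104) and TP53I3 2.04-fold lower (275 to 135). Among 24 measured apoptosis regulators only PMAIP1, which encodes the BH3-only protein NOXA, was past 2-fold (167 to 71.1, 2.35-fold lower), and the median was −0.08 (percentile 21.2). The sign of that median turned with the median over probe sets (0.056, percentile 46.55) and without probe sets that can hit several transcripts (0.12, percentile 77.25).

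The endoplasmic reticulum stress and amino acid response list stood apart on the higher side, with 21 of 27 measured genes above 0, 8 at least 2-fold higher and a median of 0.56 (percentile 100). The 8 were mostly genes known as targets of the transcription factor ATF4, a description given after their values were seen. Genes of endoplasmic reticulum chaperones and folding factors in the same list were inside 2-fold, with 7597 and 7662 for HSPA5, 1537 and 1512 for HSP90B1, 1453 and 1441 for HYOU1, 1127 and 928 for PDIA4, 1225 and 1328 for CALR and 735 and 1197 for DNAJB9. The split was not complete. Of the other members, SESN2 (279 and 266) and SLC7A5 (2905 and 2732) were not higher, and ATF4 itself had 4847 and 5450. HERPUD1, XBP1 and SEL1L had ratios of 1.43, 1.45 and 1.44. ASNS was 4.12-fold higher, the pseudokinase gene TRIB3 3.60-fold (424 to 1524), SLC7A11 3.42-fold and the glutathione-degrading enzyme gene CHAC1 3.13-fold (73.6 to 230). The CHOP gene DDIT3 (171 to 507), the mTORC1 inhibitor gene DDIT4 (500 to 1480), VLDLR (43.8 to 119) and the mitochondrial folate enzyme gene MTHFD2 (1677 to 3553) were 2.97-fold, 2.96-fold, 2.72-fold and 2.12-fold higher.

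The NRF2 and oxidative stress list had the highest median of the 25 lists at 0.82 (percentile 100), with 20 of 22 measured genes above 0 and 7 at least 2-fold higher. These were OSGIN1, SLC7A11, the aldo-keto reductase genes AKR1C1 (351.3 to 1449, 4.13-fold), AKR1C2 (241 to 985, 4.09-fold) and AKR1C3 (463 to 988, 2.13-fold), the transketolase gene TKT (3110 to 8514, 2.74-fold) and the quinone reductase gene NQO1 (802 to 1794, 2.24-fold). The AKR1C genes are close paralogs whose probe sets can bind each other's transcripts, so their separate values are uncertain. The AKR1C1 probe set used without the suffixes for shared or cross-hybridizing sequence had 13.6 and 30.1, with the untreated signal under the floor, so its log2 ratio was at least 0.45. Without such probe sets the list median was 0.74, under the 0.89 of the amino acid response list. The members below 0 were HMOX1 (431 and 400) and TALDO1 (5584 and 5031).

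In the list of xenobiotic metabolism and transport 18 of 21 measured genes lay above 0 and 5 were at least 2-fold higher, with a median of 0.61 (percentile 99.99). The aryl hydrocarbon receptor target CYP1A1 was 3.42-fold higher (93.2 to 319), the P-glycoprotein gene ABCB1 3.26-fold (25.2 to 82.3), the organic anion uptake transporter gene SLCO2B1 2.41-fold (102 to 246), ABCC3 2.14-fold (80.3 to 172) and the glutathione transferase gene GSTA1, which has close paralogs, 2.01-fold (613 to 1230). One of the 5 measured probe sets of ABCC3 went the other way (55.3 and 24.9). All 15 measured iron handling genes lay above 0, with a median of 0.56 (percentile 100). The ferric reductase gene CYBRD1 was 2.13-fold higher (96.3 to 205), and the mitochondrial iron importer gene SLC25A37 (768 and 1371), the ferrochelatase gene FECH and the ferroxidase gene HEPH (201 and 342) had ratios of 1.78, 1.76 and 1.71. The amino acid response, NRF2, xenobiotic and iron lists stood apart under all 10 alternatives.

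**Figure D3:**
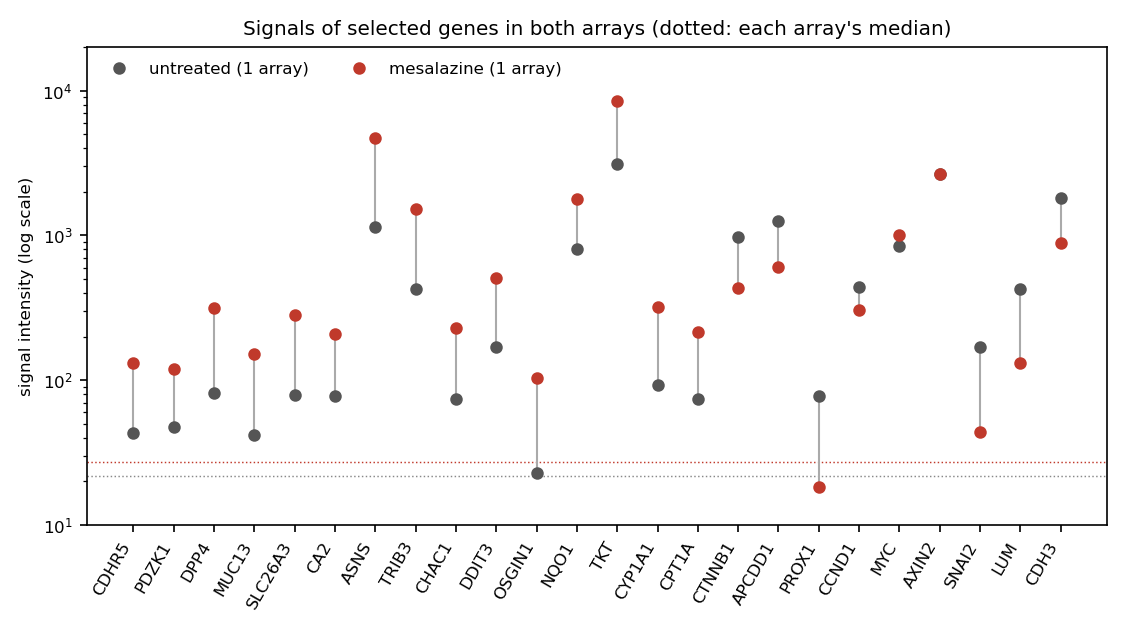
Signal intensity on a log axis (y axis) of selected genes (x axis) in the untreated array (grey) and the mesalazine array (red), with 1 array each and dotted lines at the array medians of 21.9 and 27.2. Signals of CDHR5, DPP4, ASNS and TKT were higher with mesalazine, those of CTNNB1, SNAI2, LUM and CDH3 were lower, and those of AXIN2 nearly coincided.

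The PPAR target and fatty acid oxidation list had a median of 0.21 (18 measured, percentile 95.5), and its members past 2-fold were TRIB3, also a member of the amino acid response list, and the mitochondrial acyl transfer gene CPT1A (74.3 to 215, 2.89-fold higher). PPARG, the nuclear receptor through which mesalazine is known to act in colon epithelium, had 189 and 160. This list stood apart at the 75th percentile floor, with the median over probe sets (percentile 99.95) and without probe sets that can hit several transcripts (97.55). The cholesterol synthesis list had a median of 0.11 (19 measured, percentile 96.4), with the sterol reductase gene TM7SF2 2.64-fold lower (462 to 175) and INSIG1 at 1324 and 2398.

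The mesenchymal and matrix list stood apart on the lower side, with 15 of 19 measured genes below 0 and a median of −0.38 (percentile 0.095). SNAI2, a transcriptional repressor of epithelial genes, was 3.87-fold lower (169 to 43.6), while the matrix glycoprotein gene THBS1 was at least 2.51-fold higher (16.6 and 55.1). The fibroblast marker list, included as a check for another cell type, had a median of −0.55 (12 measured, percentile 0.01), with POSTN, the proteoglycan gene LUM (425 to 132, 3.22-fold lower) and DCN (63.0 and 20.7, at least 2.31-fold lower) past 2-fold. Without probe sets that can hit several transcripts neither list stood apart (percentiles 13.675 and 13.9), and the mesenchymal list did not at the 75th percentile floor either (28.15). Cell junction genes had a median of 0.02 (23 measured, percentile 84.1). The P-cadherin gene CDH3 was 2.06-fold lower (1826 to 887), inside 2-fold after 3 of the other scalings, and the E-cadherin gene CDH1 had 8197 and 6261. The claudin genes CLDN3 (749 and 1468) and CLDN4 (680 and 1125) had ratios of 1.96 and 1.66.

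The interferon response list had a median of 0.42 (18 measured, 16 above 0, percentile 99.62). Of the 16, OAS1 (22.02 and 17.97) and IFIT3 (23.3 and 20.8) had lower treated signals and lay above 0 through the higher treated floor. The immunoproteasome gene PSMB9 was at least 4.31-fold higher (17.5 and 94.5) and IRF7 2.04-fold higher (140 to 285). The list did not stand apart with the median over probe sets or without probe sets that can hit several transcripts. The NF-kB target list had a median of 0.40 (15 measured, percentile 96.5), with IL18, an epithelial cytokine gene, 2.73-fold higher (120.5 to 329). The list stood apart only at the 75th percentile floor (median 0.60, percentile 99.95, 6 genes). Its median was 0.11 (percentile 80.5) after quantile normalization and 0.083 (77.65) after the loess correction. It was 0.12 (63.6) with the same floor for both arrays and 0.16 (39.25) without probe sets that can hit several transcripts. Under the remaining alternatives the median lay between 0.33 and 0.47. Only 5 leukocyte markers were measured, with a median of 0.37 (percentile 57.5) and CSF1R at least 2.30-fold higher (21.9 and 50.6).

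Ribosomal protein genes had a median of 0.05 (22 measured, 17 above 0, percentile 98.38), apart from random lists by position while the ratio itself was 1.04. The list did not stand apart after quantile normalization, with the median over probe sets or without probe sets that can hit several transcripts (percentile 66.25). That median was −0.0091 when the arrays were centred on their median ratio. The respiratory chain list (26 measured) had a median of −0.15 (percentile 18.9). The hypoxia and glycolysis list (28 measured) had the same rounded median of −0.15 (percentile 6.93), with no member past 2-fold, the glucose transporter gene SLC2A1 at 1324 and 686 and VEGFA at 306 and 578.

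Several list members past 2-fold came inside it under an alternative. CEBPB, GDF15, TP53I3, ABCC3, CYBRD1, IRF7 and CSF1R did so under at least 1 other scaling. MUC13, CA2, CHAC1, SLCO2B1 and SNAI2 did so at the 75th percentile floor, and PROX1, CPT1A, PMAIP1, FZD1, LUM and DCN with the median over probe sets. CDHR5, PDZK1, PROX1, PLAUR, GDF15, OSGIN1, VLDLR, ABCB1, THBS1, DCN, PSMB9 and CSF1R lay under the 75th percentile floor on both arrays. They were not measured at that floor, so it says nothing on their ratios. Every measured probe set of PROX1 and DCN had a lower treated signal that lay under the floor, so their medians are limited by the floor. The dimmer LUM probe set (32.2 and 15.2) also had its treated signal under the floor, which limits the LUM median. Without probe sets that can hit several transcripts, a dim probe set with an untreated signal under the floor stood for ASNS, and its ratio was at least 1.85.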

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

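The setting with 1 floor for both arrays was chosen after the data were seen, and the other 11 settings were not. No paired analysis was possible because each group held 1 array, and no array could be left out. Of the values for counts, list medians and the technical spread, 221 stayed within their limit, 71 moved by more and 1 changed sign after standing apart. The limit was 1.5 times for counts, and for a list median the technical SD divided by the square root of the number of its measured genes, so small shifts of long lists count as moved. Of the values for single genes 1141 moved by less than the technical SD and 88 by more. The DNA replication, mitosis, growth arrest, amino acid response, NRF2, xenobiotic and iron lists stood apart in the same direction under all 10 settings that apply to lists. Of these settings 2 (the centrings) cannot change a percentile except through the newly drawn random lists. Signal over background is unknown without detection calls, and dim genes depend on the floor. Goblet and leukocyte lists gave no value at the 75th percentile floor, where too few members were measured. Floors and size thresholds change the counts by construction. For all other values the cause was not tested.

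With quantile normalization 380 genes were higher. List medians were −0.16 for Wnt targets, 0.13 for enterocyte, −0.10 for goblet and enteroendocrine, 0.11 for NF-kB, 0.66 for amino acid response, −0.011 for respiratory chain and 0.087 for leukocyte genes. With loess on brightness 371 genes were higher, and medians were −0.18 for Wnt targets, 0.12 for enterocyte, −0.13 for goblet and enteroendocrine, 0.083 for NF-kB, −0.47 for mesenchymal, 0.18 for ribosomal, −0.064 for respiratory chain and 0.10 for leukocyte genes. Centred on the median ratio, DNA replication was −0.41 and ribosomal proteins reversed to −0.0091. Centred on the 100 normalization controls, Wnt components were −0.016, DNA replication −0.28 and mitosis −0.18.

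At the 25th percentile floor 3099 genes passed the size rule (2307 higher, 792 lower), and medians were 0.42 for enterocyte, −0.22 for mesenchymal and 0.18 for leukocyte genes. At the 75th percentile floor 200 passed (102 higher, 98 lower), and medians were −0.23 for Wnt targets, −0.028 for p53 targets, 0.13 for enterocyte, 0.60 for NF-kB, 0.71 for NRF2, 0.43 for xenobiotic and −0.14 for mesenchymal genes. With no floor 5052 passed (3271 higher, 1781 lower), the technical SD was 1.10, and medians were 0.44 for enterocyte, −0.30 for mesenchymal and 0.11 for leukocyte genes. With 1 floor for both arrays medians were 0.11 for enterocyte, 0.12 for NF-kB and 0.63 for leukocyte genes. A ratio of 1.5 gave 2968 genes (1983 higher, 985 lower) and a ratio of 3 gave 155 (103 higher, 52 lower).

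With the median over a gene's probe sets, medians were 0.41 for enterocyte, 0.40 for PPAR, −0.21 for mesenchymal, 0.056 for apoptosis, 0.23 for interferon and −0.36 for fibroblast genes. Without probe sets for shared or cross-hybridizing sequence, medians were 0.61 for brush border, 0.41 for enterocyte, 0.30 for PPAR, 0.16 for NF-kB, 0.89 for amino acid response, 0.74 for NRF2, 0.69 for iron, −0.083 for mesenchymal, 0.12 for apoptosis, −0.011 for respiratory chain, −0.10 for fibroblast and 0.65 for leukocyte genes. The fibroblast, mesenchymal, interferon and ribosomal lists no longer stood apart there, while the brush border, enterocyte and PPAR lists did.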

Other observations

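The tests on brightness (olfactory receptor genes), dim genes, fibroblasts and the NRF2 list (scaling, paralogs and shared genes) were chosen after the result was seen. The tests on the 5 further gene lists, which were compiled after the first lists had been seen, were written before their values, except for SLC1A1, whose ratio was known.

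The hypothesis that an ATF4 programme extended beyond the amino acid response list was tested on tRNA synthetase genes known as ATF4 targets. Of 11 measured 9 lay above 0, with a median of 0.30 (percentile 99.92, and 99.95 or more after quantile normalization and loess). Examples were the alanyl-tRNA synthetase gene AARS1 (1238 and 2373) and the seryl-tRNA synthetase gene SARS1 (1001 and 1465). The 6 measured synthetases outside that set all lay below 0, with a median of −0.38 (percentile 1.9, up to 2.6 under quantile normalization), as for VARS1 (477 and 343) and KARS1 (7451 and 5813), which argues against a rise of all cytosolic synthetases. These values are consistent with an ATF4 programme, on 1 array per group.

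Lysosome and autophagy genes had a median of 0.21 (percentile 99.27, 14 of 21 measured above 0), with TFEB, a master regulator of lysosomal genes, 2.85-fold higher (32.2 to 91.9) and WIPI1 2.30-fold higher (315 to 724). The autophagy receptor gene SQSTM1 had 998 and 1830 and GABARAPL1 507 and 967, and the lysosomal protease gene CTSL had 1668 and 3036. LAMP1 (5477 and 4930), CTSD (454 and 416) and ATG12 (972 and 681) lay below 0. Amino acid transporters had a median of 0.22 (14 measured, percentile 98.06), but the percentile was 95.78 without the glutamate transporter gene SLC1A1 (67.5 and 250.2), so that hypothesis stays open. SLC6A9 was 2.22-fold higher (47.8 to 106) and SLC36A1 2.12-fold lower (316 to 149). Proteasome subunits, known as NRF2-related targets in some settings, did not go with the NRF2 list. Only 3 of 25 measured subunits lay above 0, with a median of −0.29 (percentile 0.46), such as PSMD1 (2017 and 1331).

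More genes were at least 2-fold higher than lower with mesalazine, mostly dim ones. Olfactory receptor genes, which colon cells are not expected to express, had a median unfloored log2 ratio of 0.65 over 82 genes (bootstrap 95% interval over genes 0.24 to 1.05, 52 above 0), but only 11 were measured and the median signals of the 82 were 5.80 and 11.1, under the floors. These values restate the shift of dim signals, and the even split after loess follows from its centring, so a brightness-dependent difference between the arrays stays open. Of the 617 higher genes 363 stayed at least 2-fold higher after loess, and 222 of the 233 lower genes stayed lower. A general response of dim genes to mesalazine cannot be told apart from it with 1 array per group.

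The fibroblast marker list was lower with mesalazine. Fibroblasts in the untreated culture would bring abundant VIM and LGALS1, but VIM (40.0 and 21.6) lay at percentile 59.5 of the untreated array and LGALS1 (3.90 and 13.5) at 21.98, which argues against them, although COL1A1 (1344 and 873) and COL1A2 (1141 and 729) were bright in both arrays. The highest percentile of the list after quantile normalization and loess was 0. The random lists were matched on brightness and largely move with such a correction, so this check of scaling between the arrays is weak. Probe sets that may hit several transcripts stay open, because without them the percentile was 13.9 over 8 genes, while both other probe sets of the lower genes that could be checked were lower. A lower expression of these genes by the Caco2 cells themselves is an untested hypothesis.

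The NRF2 list was higher with mesalazine. Without AKR1C1, AKR1C2, AKR1C3 and the genes it shared with other lists, the 17 remaining genes had a median of 0.68 (percentile 100), which argues against cross-hybridization among AKR1C genes or shared members as the whole cause. The lowest percentile after quantile normalization and loess was 100, so the list differed from genes of like brightness under both scalings. The random lists were matched on brightness and largely move with such a correction, so this check of scaling between the arrays is weak. An NRF2 response to mesalazine may be present, as a hypothesis found and tested on the same arrays.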
